A study of Mus musculus with 96 samples.

How the data were processed

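Barcodes integrated into the genome of leukaemia cells were amplified from genomic DNA and counted by sequencing. Each barcode was taken to mark 1 transduced founder cell and its descendants, called a clone here. Whether some cells carried more than 1 barcode was not examined. The labels give genomic DNA as the source, but their extraction protocol describes a single-cell droplet preparation, so how the DNA was obtained is uncertain. The submitted sample records comprise 96 sequencing libraries, made as PCR duplicates of 45 mouse tissues and 3 cell pools taken before transplantation. The deposited tables hold 48 distinct columns, 1 per mouse tissue or pool, in which the authors had already filtered the barcodes and collapsed the PCR duplicates. Whether duplicates were summed or averaged is not stated. The deposited values are in CPM (counts per 1000000 barcode reads), which the authors scaled so that every column sums to 1000000. The submitters' processing notes name Bowtie 1.2.2 and R 3.6 without giving aligner settings, the barcode reference or the filters. The table of each host was deposited separately, and the columns of the 3 pools were identical in both.

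Barcode names gave the library of each clone. Per the labels, GFP barcodes belonged to cells that started as LSK and mCherry barcodes to cells that started as GMP. The tables listed 4675 barcodes in all, 1331 of them in the LSK (GFP) library, 3078 in the GMP (mCherry) library and 266 with a BFP name that no sample label mentions. The table of the NSG mice listed 2844 barcodes and that of the Ptprca mice 4382, with 2551 in both. A barcode absent from a table was taken as 0. The values of each column were whole multiples of 1 step, taken as 1 read (or, had duplicates been averaged, a fraction of 1), for 100% of the listed values within 0.01 of a read. This gave 4257581 to 8499553 reads per column. A clone with 0 reads may hold a share of up to 3 reads of the total, which is 3.53e-05% to 7.05e-05% depending on the library. Such limits and the 95% confidence intervals (Wilson) cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

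The mouse was the unit of replication, with bone marrow and spleen averaged to 1 value per mouse. Mouse 24 had a spleen library only. The LSK share was the LSK-library part of LSK plus GMP reads, tested as log2 odds. Effective clones were the exponential of the Shannon entropy of barcode shares, which is the number of equally large clones that would give the same diversity. Detected clones were the barcodes at or over 100 CPM. Differences between hosts were permuted within the origin of the cells and differences between origins within host, all by exact two-sided permutation tests. Comparisons of mice with their pool, and of bone marrow with spleen, used exact two-sided sign-flip permutation tests. The p-values of these 11 tests were adjusted together by the Benjamini-Hochberg method.

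Overlap of leading clones was the mean number of clones shared by the top 10 of a pair of mice. It was compared with 10000 draws in which each mouse's fold over the pool was shuffled among clones of similar pool abundance (10 bins), one-sided. The share that single-origin top 10 clones held in mixed recipients was compared with 10000 draws of clones matched on pool abundance, one-sided. Single clones were compared with limma 3.58.1 (lmFit and eBayes with trend, two-sided) on log2 of CPM plus 10, after rescaling to the reads of the clone's own library. Clones with a mean at or over 100 CPM were tested, and those with an adjusted p under 0.05 were called. Percentages of leading clones in mixed recipients are of their own library.

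Named clones followed a rule fixed before the data were examined. For each library it took the 5 clones with the highest mean percentage over the single-origin mice, the 5 highest over the mixed recipients, and up to 3 called clones per direction of each limma comparison. Other clones named below were chosen after their values were seen.

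Alternatives fixed before the data were examined were other pseudocounts (1 and 100 CPM), other minima (10 and 1000 CPM, or none), each tissue alone, each host or recipient type alone, the inverse Simpson index, CPM as deposited, eBayes without trend, the top 5 or 20 clones, Spearman correlation, values relative to the pool, and each mouse left out in turn. Added after seeing the data were edgeR 4.0.16 on the recovered reads with and without TMM scaling, centring of each mouse on its median clone, each tissue alone for the shares of the leading clones, and leaving out 8 libraries. Those 8 held at least 0.1% of reads from the library that the mouse did not receive, or at least 1% in barcodes found in no pool. The tests were checked on simulated data. With no true difference, 5% of 200 simulated host comparisons of effective clones had a p under 0.05. For limma the share of false calls, pooled over 20 simulated runs per setting, was above 5% in most settings. It ranged from 2.38% to 27.3% in the competition comparisons and from 3.85% to 16.7% between hosts. BFP barcodes entered library totals and clone numbers, and so the comparisons of clone numbers, but neither the LSK share nor the limma tests. Barcodes of the library that a mouse did not receive entered its clone numbers as well. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.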

Results

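The series followed mouse leukaemias driven by MLL-AF9, a fusion oncogene, that were started from either of 2 kinds of blood progenitor and labelled with SPLINTR DNA barcodes. LSK cells are an immature population that includes haematopoietic stem cells. GMP cells are granulocyte-monocyte progenitors, further along the myeloid lineage. Leukaemias of LSK origin, of GMP origin or of both mixed were transplanted into Ptprca mice, an immunocompetent strain, or NSG mice, which lack B, T and NK cells. Barcodes were then counted in bone marrow and spleen. Ptprca recipients comprised 3 mice with LSK cells, 4 with GMP cells and 4 with both. NSG recipients comprised 4 mice of each kind. Of these 23 mice, 22 had both tissues. Each library rested on 4257581 to 8499553 barcode reads. The design names a competition between cells of origin, which the mixed recipients address.

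LSK- and GMP-derived cells both persisted in all 8 mixed recipients. The pool put into these mice held 50.6% LSK-library reads (95% interval by Wilson 50.56 to 50.66, 1 sample). In Ptprca recipients the LSK share was 40.2% ± 2.26 (SD, n = 4), and the mean of each mouse lay below the pool. In NSG recipients it was 58.6% ± 9.58 (SD, n = 4), and the mean of each mouse lay above the pool, mouse 21 by little at 51.1%. Much of the NSG rise rested on mouse 23 at 72.6%, without which the NSG mean was 53.9% ± 2.46 (SD, n = 3) and 0.19 log2 odds above the pool. Single tissues overlapped the pool, with 43.9% in the bone marrow of NSG mouse 21 and 49.3% in the spleen of NSG mouse 22. Over both hosts no difference of the LSK share from the pool was detected (log2 odds -0.06, exact sign-flip permutation p = 0.875, adjusted 0.875, 4 of 8 mice below). Within each host the log2 odds differed from the pool by -0.61 ± 0.13 in Ptprca and 0.50 ± 0.62 in NSG mice (SD, n = 4), each with an exact permutation p of 0.125, the smallest that 4 mice allow. The difference between hosts was -1.11 log2 odds, with the smallest exact permutation p that 4 against 4 mice allow, 0.0286, and an adjusted p of 0.0524, which fails the threshold. Without mouse 19 it was -1.05 (exact permutation p = 0.0571), and in spleen alone -1.02 (exact permutation p = 0.0571).

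**Figure D1:**
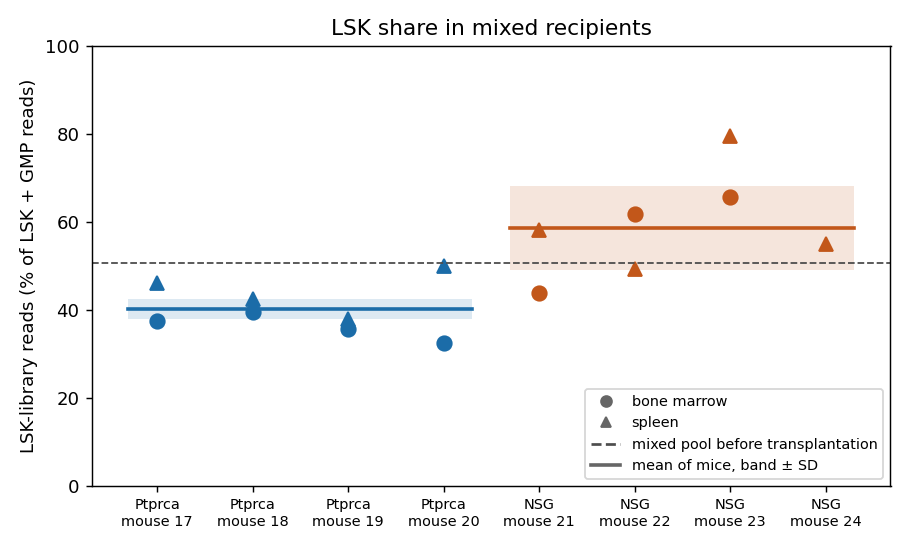
LSK-library reads as a percentage of LSK plus GMP reads (vertical axis) in each mixed recipient (horizontal axis), with circles for bone marrow and triangles for spleen. Solid lines and bands give the mean ± SD of the mice of each host, 40.2% in Ptprca and 58.6% in NSG mice, and the dashed line gives the pool at 50.6%.

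Every recipient held far fewer effective clones than the pool it was given. Effective clones fell from 296 in the LSK pool, 269 in the GMP pool and 579 in the mixed pool to between 5.76 and 18.5 per mouse, on average 37.1-fold lower (fell by 5.21 on the log2 scale, 23 of 23 mice, sign-flip permutation p = 2.38e-07, the smallest 23 mice allow, adjusted 2.62e-06). That p-value leaves out the spread of the pools, since all 23 mice were set against only 3 pool samples. The 6 leading LSK clones ranked 3, 44, 48, 60, 142 and 382 in their pool, which held 679 clones at or over 100 CPM. The 6 leading GMP clones ranked 1, 2, 4, 41, 50 and 292 in theirs, which held 607. The LSK clone GFP_Barcode_1859 ranked 60 in the LSK pool at 0.462% and held 27.3% ± 10.7 (SD, n = 7) over the LSK recipients. GFP_Barcode_29850 rose from 0.563% to 18.1% ± 10.3, GFP_Barcode_7785 from 2.08% to 16.5% ± 6.49, GFP_Barcode_100907 from 0.533% to 15.8% ± 5.03 and GFP_Barcode_2255 from 0.0391% to 2.67% ± 1.81 (SD, n = 7 each). These means cover both hosts, and their order held in neither, with GFP_Barcode_1859 first in Ptprca and GFP_Barcode_29850 first in NSG mice. Of the GMP clones, mCHERRY_2_Barcode_626161 went from 2.97% of the pool to 29.0% ± 2.63 and mCHERRY_2_Barcode_283858 from 0.491% to 28.0% ± 2.08 over the GMP recipients (SD, n = 8). The next were mCHERRY_2_Barcode_1204592 at 10.3% ± 2.98, mCHERRY_2_Barcode_88201 at 6.31% ± 1.91 and mCHERRY_2_Barcode_205681 at 4.97% ± 1.31 (SD, n = 8 each). The largest GMP pool clone, mCHERRY_2_Barcode_4128, held 3.24% of the pool and 4.70% ± 2.04 in the mice. The first 3 GMP clones kept this order in each host, while mCHERRY_2_Barcode_4128 ranked 4 in Ptprca (5.70%) and 7 in NSG mice (3.70%), and mCHERRY_2_Barcode_88201 ranked 6 (5.28%) and 4 (7.33%). The share of mCHERRY_2_Barcode_283858 was 23.6% ± 5.22 in bone marrow and 32.5% ± 4.29 in spleen (SD, n = 8).

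The same clones led in separate mice. A pair of Ptprca recipients shared on average 7.67 of their top 10 clones with LSK cells, 8.83 with GMP cells and 9.0 with both. Pairs of NSG recipients shared 7.33, 7.83 and 8.5. Draws matched on pool abundance gave 0.27 to 0.57, and each of the 6 recipient groups had a permutation p of 1e-04, the smallest the draws allow (adjusted 1e-04). The top 10 clones of a mouse held between 80.6% ± 2.33 of reads in mixed Ptprca recipients (SD, n = 4) and 96.1% ± 0.92 in NSG recipients of LSK cells (SD, n = 4). By mean share, Ptprca and NSG recipients had 8 of their top 10 clones in common for LSK cells, 7 for GMP cells and 9 for both. The test does not tell clones that were fit before transplantation from differences between a barcode's share of pool reads and its share of engrafting cells.

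The clones that led without a competitor also led with one. The 10 leading clones of the LSK recipients held 86.1% ± 3.55 of LSK-library reads in mixed Ptprca mice and 92.5% ± 1.27 in mixed NSG mice (SD, n = 4), against 84.2% ± 1.76 (SD, n = 3) and 95.1% ± 1.12 (SD, n = 4) in the LSK recipients themselves. The 10 leading GMP clones held 92.6% ± 2.21 of GMP-library reads in mixed Ptprca and 94.0% ± 2.15 in mixed NSG mice (SD, n = 4). In the mixed pool these lists held 5.40%, 5.41%, 10.3% and 11.8% of their library, in the order named, and each of the 4 tests had a permutation p of 1e-04, the smallest the draws allow (adjusted 1e-04).

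Few single clones were called as differing in their share of the library between competition and growth alone. The mixed pool held 50.6% LSK-library reads, so each clone may also have been given at a lower dose in mixed recipients. Competition and a lower dose cannot be told apart in these comparisons. In Ptprca mice, 2 of 101 tested GMP clones were called lower in competition by limma, mCHERRY_2_Barcode_51624 (0.00862% ± 0.0105 against 0.0951% ± 0.0206, adjusted p = 0.0343) and mCHERRY_2_Barcode_138752 (0.00598% ± 0.0076 against 0.0683% ± 0.0177, adjusted p = 0.0343; SD, n = 4 each). In NSG mice, 2 of 48 GMP clones were called lower, mCHERRY_2_Barcode_64434 (0.00195% ± 0.00187 against 0.275% ± 0.122, adjusted p = 0.0102) and mCHERRY_2_Barcode_74010 (0.024% ± 0.0474 against 0.564% ± 0.497, adjusted p = 0.0157; SD, n = 4 each). These 2 were above 0 in 3 and 4 of the 7 mixed NSG libraries, in the order named. None of 143 LSK clones in Ptprca and none of 50 in NSG mice was called by limma, with 14 and 6 at an unadjusted p under 0.05, and edgeR called none in any of the 4 comparisons. The largest LSK clone, GFP_Barcode_1859, held 48.5% ± 2.92 of the LSK library in mixed Ptprca mice (SD, n = 4) and 38.0% ± 3.69 in LSK recipients (SD, n = 3), a difference that missed the threshold (limma adjusted p = 0.0779). The GMP calls in Ptprca mice were lost without any 1 of mice 5, 6, 7, 17, 18 and 19 and numbered 7 without mouse 8, and those in NSG mice were lost without mouse 16 or 21. Over the alternatives, the 2 clones called in Ptprca mice ranged from -4.47 to -1.76 and from -4.45 to -1.95 log2. The 2 called in NSG mice ranged from -8.07 to -4.06 and from -8.55 to -2.41 log2, in the order named. The median GMP clone was itself lower in competition (-0.69 log2 in Ptprca, -0.99 in NSG), and with each mouse centred on its median clone 4 and 5 GMP clones were called, all higher, while the 4 clones named here kept their direction but not the call. In simulated data limma recovered 14.5% to 46.2% of changes of 3 log2 units and 2.07% to 20.5% of changes of 1 or 2 units in these 4 comparisons. Of the clones it called there, 2.38% to 27.3% were false, and 12.5% to 20% for GMP clones in NSG mice. These shares pool the calls of 20 runs per setting and rest on few calls where few changes were recovered. A pooled share is also not the mean per run that the threshold of 5% addresses. Single calls may therefore be weaker than that threshold implies.

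Ptprca mice kept more clones than NSG mice. Detected clones numbered 92.3 ± 6.25 in Ptprca (SD, n = 3) and 39.4 ± 6.84 in NSG recipients of LSK cells, 72.9 ± 6.46 and 33.5 ± 2.42 with GMP cells, and 111 ± 4.11 and 43.5 ± 9.57 with both (SD, n = 4 each). The hosts did not overlap in any of these 3 comparisons, and the mean difference was 2.29-fold (permutation p = 5.83e-06, the smallest the design allows, adjusted 2.14e-05). Effective clones numbered 12.8 ± 1.58 against 6.61 ± 0.58 with LSK cells, 9.55 ± 0.75 against 7.27 ± 0.57 with GMP cells and 16.2 ± 1.77 against 11.7 ± 1.84 with both, 1.45-fold higher in Ptprca mice (0.54 log2, permutation p = 5.83e-06, adjusted 2.14e-05). That difference was 0.15 log2 in spleen alone (permutation p = 0.125), and 0.10 log2 with the inverse Simpson index, which gives large clones more weight (permutation p = 0.158). The largest clone held 38.0% ± 3.69 (SD, n = 3) in Ptprca and 29.0% ± 2.75 in NSG recipients of LSK cells, 31.5% ± 0.62 and 32.4% ± 2.55 with GMP cells, and 23.2% ± 0.56 and 21.4% ± 5.88 with both (SD, n = 4 each). The mean difference of 3.29 points did not pass (permutation p = 0.0585, adjusted 0.0919), though it passed before adjustment in spleen alone (7.01 points, permutation p = 0.0209), in LSK recipients alone (8.98 points, exact permutation p = 0.0286, the smallest allowed), and without mouse 15 (3.67 points, permutation p = 0.0262) or mouse 23 (4.26 points, permutation p = 0.00335). Each host came in its own table, and the labels give no preparation batch. A difference in preparation that followed the host could not be told apart from the host.

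**Figure D2:**
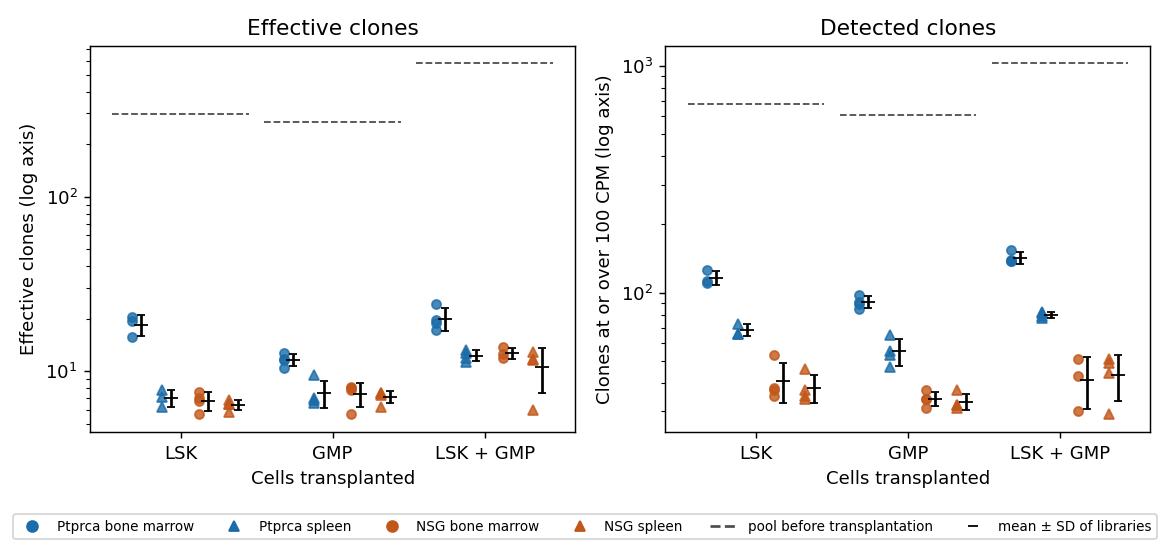
Effective clones (left) and clones at or over 100 CPM (right), both on log axes, for each library by the cells transplanted, with circles for bone marrow, triangles for spleen, blue for Ptprca and orange for NSG mice. Black marks give the mean ± SD of the libraries, and dashed lines give the pools, at 296, 269 and 579 effective clones.

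The hosts also differed in which clones were large. Among LSK clones, GFP_Barcode_29850 held 7.90% ± 2.40 in Ptprca (SD, n = 3) and 25.7% ± 5.23 in NSG mice (SD, n = 4; limma adjusted p = 0.000963), GFP_Barcode_100907 10.7% ± 1.31 and 19.7% ± 1.70 (adjusted p = 0.00321) and GFP_Barcode_20873 0.477% ± 0.427 and 1.52% ± 0.479 (adjusted p = 0.0317). The call of GFP_Barcode_20873 was lost in 8 of 19 alternatives, among them bone marrow alone and leaving out mouse 2, 3, 11 or 12 (adjusted p up to 0.122), and that of GFP_Barcode_100907 was lost without trend (adjusted p = 0.192). GFP_Barcode_1859, the largest LSK clone in Ptprca and the fourth in NSG mice, went the other way by share, with 38.0% ± 3.69 in Ptprca and 19.3% ± 4.63 in NSG mice (1.0 log2, limma adjusted p = 0.00328), but was -2.26 log2 relative to the median clone. Clones higher in Ptprca mice were mostly small, led by GFP_Barcode_3877 (0.439% ± 0.0804 against 0.000195% ± 0.00021), GFP_Barcode_15551 (0.144% ± 0.0632 against 0.000127% ± 0.000245) and GFP_Barcode_814 (0.417% ± 0.466 against 0.00198% ± 0.00333). Among GMP clones, mCHERRY_2_Barcode_307110 reached 3.95% ± 1.46 in Ptprca and 0.0241% ± 0.0405 in NSG mice (SD, n = 4 each; limma adjusted p = 6.22e-05), ahead of mCHERRY_2_Barcode_181301 (0.183% ± 0.0847 against 3.79e-05% ± 6.51e-05) and mCHERRY_2_Barcode_10809 (0.16% ± 0.0939 against 0.000445% ± 0.000791). In the other direction, mCHERRY_2_Barcode_457303 held 0.0358% ± 0.0472 in Ptprca and 2.33% ± 2.11 in NSG mice (limma adjusted p = 0.000643), mCHERRY_2_Barcode_74010 0.00114% ± 0.00141 and 0.564% ± 0.497, and mCHERRY_2_Barcode_336132 0.000263% ± 0.000516 and 0.0797% ± 0.0908. Several of the low shares rested on few libraries. GFP_Barcode_3877, GFP_Barcode_15551 and mCHERRY_2_Barcode_181301 were above 0 in 3 of 8 NSG libraries each, mCHERRY_2_Barcode_10809 in 4 and GFP_Barcode_814 in 6. Of 8 Ptprca libraries, mCHERRY_2_Barcode_336132 was above 0 in 3 and mCHERRY_2_Barcode_74010 in 5. The size of such differences is therefore uncertain. The 2 leading GMP clones did not differ past the threshold, with 28.7% ± 2.46 and 29.4% ± 3.09 for mCHERRY_2_Barcode_626161 (limma adjusted p = 0.788) and 28.0% ± 2.25 and 28.1% ± 2.32 for mCHERRY_2_Barcode_283858 (adjusted p = 0.967).

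In all, limma called 55 of 103 LSK clones between hosts, 52 higher and 3 lower in Ptprca mice, and 49 of 88 GMP clones, 42 higher and 7 lower. These splits depend on the scaling and on the abundance of the clones tested. The median tested clone was 3.26 log2 higher in Ptprca mice for LSK and 2.93 for GMP cells, and with each mouse centred on its median clone 1 LSK clone was higher and 18 lower, and 2 GMP clones higher and 31 lower. With edgeR and TMM scaling 17 LSK clones were higher and 7 lower, and 30 GMP clones higher and 11 lower. Among clones with a mean at or over 1000 CPM, 14 LSK clones were higher and 3 lower and 4 GMP clones higher and 4 lower, the median GMP clone being 0.064 log2 higher. In spleen 19 LSK clones were higher and 3 lower, and 16 GMP clones higher and 9 lower. The 12 clones named for this comparison by the rule kept their direction under each of these scalings, but GFP_Barcode_15551, GFP_Barcode_814 and mCHERRY_2_Barcode_10809 lost the call with centring (2.36, 2.28 and 1.76 log2, adjusted p = 0.151, 0.291 and 0.153), the first pair also with TMM (adjusted p = 0.0562 and 0.0671). In bone marrow alone mCHERRY_2_Barcode_74010 and mCHERRY_2_Barcode_336132 were not called (adjusted p = 0.117 and 0.0817). The GMP count was 30 without mouse 5, and 28 without the 8 libraries that held barcodes of the other library or of no pool.

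Recipients of the LSK pool and of the GMP pool differed in detected clones, and no difference in effective clones was found. The series holds a single pool per origin, each with its own barcode library. The tests therefore measure the spread between mice, not between leukaemias of the same origin. LSK recipients held 1.21-fold more detected clones than GMP recipients of the same host (0.28 log2, exact permutation p = 0.00327, adjusted 0.00718), with no overlap in Ptprca mice and overlap in NSG mice. The direction turned when clones down to 10 CPM were counted (-0.06 log2, exact permutation p = 0.825) or all above 0 (-0.13 log2, exact permutation p = 0.48), and relative to the pools it was 0.12 log2 (exact permutation p = 0.16). Effective clones differed by 0.08 log2 (exact permutation p = 0.396, adjusted 0.484), a mean of opposite signs, 0.30 in Ptprca (exact permutation p = 0.0857) and -0.13 in NSG mice (exact permutation p = 0.2), which differed between hosts (permutation p = 0.00794). The largest clone differed by 1.54 points (exact permutation p = 0.459, adjusted 0.505). In Ptprca mice alone the largest clone held 6.48 points more in LSK than in GMP recipients (exact permutation p = 0.0286, the smallest allowed), and in NSG mice the difference was -3.40 points (exact permutation p = 0.143).

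Bone marrow held more clones than spleen, chiefly in Ptprca mice. Effective clones were 1.43-fold higher in bone marrow over all 22 mice with both tissues (0.51 log2, 19 of 22 mice, sign-flip permutation p = 6.53e-05, adjusted 0.00018). With no replicate block, permuting tissue labels over all libraries and not within mouse, the permutation p was 0.0028 for the same 0.51. In Ptprca mice the marrow was higher in all 11, by 0.87 ± 0.39 log2 (SD, permutation p = 0.000977, the smallest 11 mice allow). In NSG mice it was higher in 8 of 11, by 0.16 ± 0.33 log2 (SD, permutation p = 0.119). In Ptprca recipients of LSK cells, bone marrow had 18.5 ± 2.49 and spleen 7.06 ± 0.79 effective clones (SD, n = 3), and the largest clone held 28.0% ± 4.70 and 48.0% ± 3.71. The difference between hosts in this tissue effect was 0.73 log2 (permutation p = 0.000373).

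**Figure D3:**
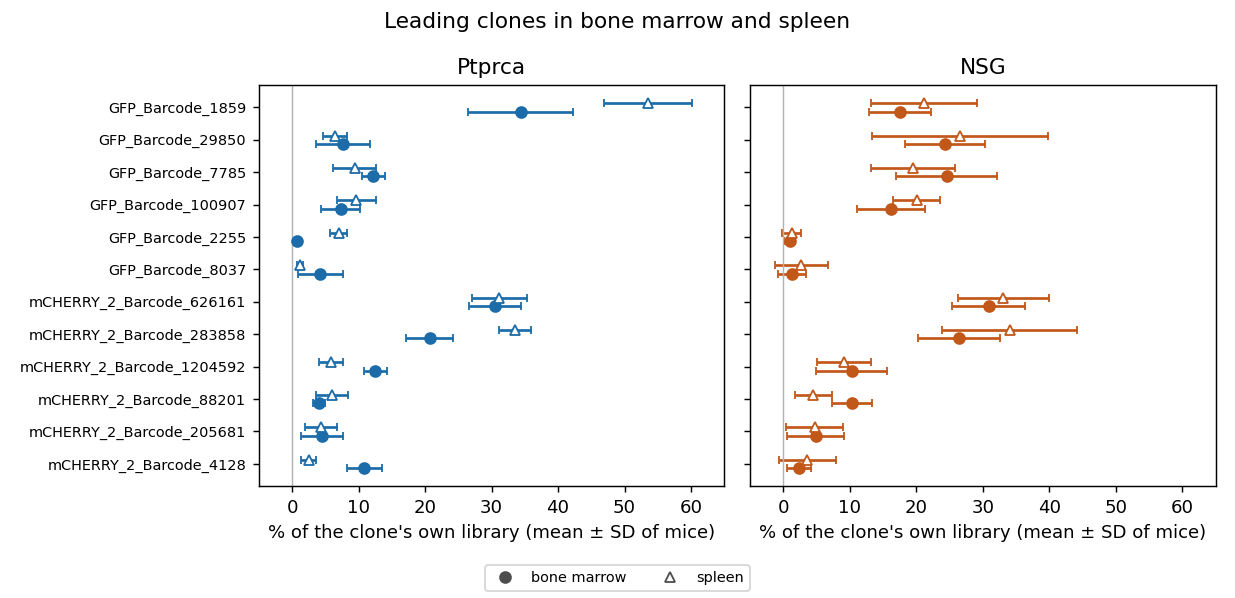
Share of the 12 leading clones in their own library (horizontal axis, mean ± SD of mice given that origin alone or mixed) in bone marrow (filled circles) and spleen (open triangles) of Ptprca (left) and NSG mice (right). In Ptprca mice GFP_Barcode_2255 averaged 0.706% in bone marrow and 6.99% in spleen, and mCHERRY_2_Barcode_4128 averaged 10.8% and 2.49%.

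Over all groups, the spleen and marrow of 1 mouse were not detectably more alike than those of separate mice of a group. Bray-Curtis similarity of bone marrow with spleen averaged 0.723 ± 0.086 within a mouse and 0.712 ± 0.063 with the spleens of the other mice (SD, n = 22), a difference of 0.0109 (sign-flip permutation p = 0.293, adjusted 0.403, 13 of 22 mice higher). By group the difference ranged from -0.0199 in NSG recipients of GMP cells to 0.0687 in NSG recipients of LSK cells, where it was higher in 4 of 4 mice (0.838 ± 0.106 against 0.769 ± 0.0791, SD, n = 4, exact permutation p = 0.125, the smallest 4 mice allow). By Spearman correlation over all pool barcodes, which weighs small clones like large ones, the difference was 0.0774 (permutation p = 0.0053). Mice of a group were compared with each other's spleens, so these differences are not independent. The sign-flip tests leave this out, and their p-values are approximate.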

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

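The tests for preparation batch, for 1 clone of each library and for barcodes of the other library were chosen after the results were seen. The others were planned before.

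NSG mice held fewer detected clones than Ptprca mice in each of the 3 kinds of recipient (2.29-fold). Sequencing depth is argued against, since NSG libraries were the deeper ones (6893914 ± 803804 against 6545726 ± 831997 reads, SD, n = 23 and 22 libraries) and thinning all to 5239254 reads left a difference of 1.21 log2 in barcodes with at least 1 read (1.15 unthinned). Counting only the 2551 barcodes listed in both tables gave 1.19 log2, against the separate filtering of the tables, and leaving out the 10 most abundant clones of each library gave 1.36 log2, against large clones crowding out small ones (permutation p = 5.83e-06 for each, the smallest allowed). A preparation batch that follows the host cannot be told apart from the host, because the labels give no batch. That 0 mouse libraries appear in both tables was fixed by the split of the tables by host, so it decides nothing. The match of foreign barcodes in Ptprca GMP mouse 8 to NSG LSK mouse 9 (similarity 0.943) bears on libraries of both hosts sharing some step but not on every step. The host itself, which differs in immune cells and strain, remains open and was not tested otherwise.

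The mean LSK share of mixed recipients lay below the pool in Ptprca and above it in NSG mice. The difference between hosts was -1.11 log2 odds (exact permutation p = 0.0286, the smallest allowed). Neither host alone differed detectably from the pool (exact permutation p = 0.125 each, the smallest allowed). The NSG value against the pool fell from 0.50 to 0.19 log2 odds without mouse 23. With any 1 of 165 LSK clones and any 1 of 155 GMP clones left out, the weakest difference was -0.74 (without GFP_Barcode_29850 and mCHERRY_2_Barcode_307110, exact permutation p = 0.0286), which argues against 1 clone of each library as the whole source. Leaving out single LSK clones weakened the difference by 0.31 (GFP_Barcode_29850), 0.30 (GFP_Barcode_7785) and 0.11 (GFP_Barcode_100907), and the next by 0.023. Leaving out these LSK clones together was not tested, so a difference resting on a few LSK clones stays open. With each mouse left out in turn the weakest difference was -0.81 (without mouse 23), which argues against 1 mouse as the whole source. Host and preparation stay open together here as well, so a host effect on the competition is a hypothesis only, and its adjusted p of 0.0524 fails the threshold.

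Single-origin mice held a few barcodes of the library they did not receive, at most 0.944% of reads, in the bone marrow of Ptprca GMP mouse 6, against 0.00209% and 0.0137% in the single-origin pools. In 6 libraries the share was at least 0.1%, and in 0 of these 6 mice did the other tissue reach that level (0.00982% to 0.0415%), which argues against other-origin cells among those transplanted. In 4 of the 6, the foreign barcodes had the profile of a mouse library of the other origin, with Bray-Curtis similarities of 0.818 to 0.943, consistent with carry-over between samples of the series. In Ptprca GMP mouse 8 the main foreign barcode was GFP_Barcode_148344, which was abundant in NSG LSK mouse 9 alone. In the other 2 the highest similarity was 0.0214, against carry-over of leading clones. The measure follows large clones and does not decide on small ones. The main foreign barcode in the spleen of NSG LSK mouse 10, mCHERRY_2_Barcode_473069 (130 CPM), was highest elsewhere in the spleen of mixed Ptprca mouse 18 (555 CPM). In Ptprca GMP mouse 6, 82.5% of the foreign reads came from GFP_Barcode_167047 alone, whose source stays open.

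A test of far values was made in 30 combinations of a group of 4 libraries and a measure, and found 7. Chance gives about 1 in 20, and the measures of a library are not independent. The bone marrow of NSG GMP mouse 15 had 5.69 effective clones, below the other 3 mice (7.76 to 8.13). The bone marrow of NSG LSK mouse 12 had 53 detected clones, above the others (35 to 38). In spleens of NSG GMP recipients, mouse 14 had 6.28 effective clones (others 7.30 to 7.47) and mouse 13 had 37 detected clones (others 31 to 32). These counts include barcodes of the other library, 0.462% of reads in the spleen of mouse 13 and 0.538% in that of mouse 14. In the marrow of mouse 12 they made up 0.103%. The largest such barcode was at 1207, 1169 and 250 CPM, in the order named, and counts without them were not made for these libraries. The largest clone held 38.9% of the spleen of mixed NSG mouse 23 (others 17.7% to 21.1%). The bone marrow of mixed Ptprca mouse 20 had 155 detected clones (others 138 to 139). The spleen of Ptprca GMP mouse 7 had 9.48 effective clones (others 6.60 to 6.99), and 7.26 with barcodes of no pool left out, a value computed after (others 6.49 to 6.97).

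The difference of bone marrow minus spleen was larger in Ptprca than in NSG mice by 0.73 log2 for effective clones (permutation p = 0.000373) and by 0.72 log2 for detected clones (permutation p = 1.17e-05), and it differed by -6.88 points for the largest clone (permutation p = 0.0377). The difference of Ptprca minus NSG mice was larger with LSK than with GMP cells by 0.43 log2 for effective clones (permutation p = 0.00794) and by 9.88 points for the largest clone (permutation p = 0.00048), while for detected clones it was larger by 0.12 log2 and did not pass (permutation p = 0.434). The p-values of this last comparison came from random permutations of residuals, and no p-value in this paragraph was adjusted.

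Barcodes with a BFP name, which entered clone numbers but not the LSK share, were present in all 45 mouse libraries. They were highest in the spleen of NSG GMP mouse 15, at 386 CPM against 15.3 to 70.2 CPM in the pools. Barcodes found in no pool made up 1.06% of reads in the spleen of mixed Ptprca mouse 18 (552 barcodes, 535 of them of the GMP library, 1 also in its bone marrow). They made up 2.92% in the spleen of Ptprca GMP mouse 7 (903 barcodes, 896 of the GMP library, 8 also in its bone marrow), and at most 0.401% in any other mouse library. These 2 spleens shared 35 such barcodes.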

How the results depend on the processing

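The 110 alternatives to the shared top 10 clones and to the carry of single-origin clones kept direction and call, as did those to the loss of clones from the pool (28), to detected clones between hosts (33) and to effective clones between tissues (27). Clones named from limma kept their direction in all 308 alternatives and their side of the threshold in 242. The edgeR fits, median centring, each tissue for leading clones and the 8 libraries left out were chosen after seeing the data. Using only 1 PCR duplicate was not run, because the deposited columns had been collapsed. None of the 8 libraries is from Ptprca LSK or mixed NSG recipients, so for the shared clones of these mice that alternative was not run. With at least 4257581 reads per library, counting error alone limits an unseen clone to 7.05e-05% of all reads or less. For shares of a clone's own library the limit is higher in mixed recipients, on average 0.000117% for GMP clones in NSG mice. Neither limit covers the authors' filter of barcodes. The 3 or 4 mice per group limit the exact p-values. For the values below the cause was not tested, except that fewer mice or clones enter where mice, tissues or clones are left out.

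In bone marrow alone the largest clone differed by -1.52 points (LSK minus GMP) and -0.57 points (Ptprca minus NSG). In spleen alone the LSK share against the pool was 0.13, between hosts -1.02, effective clones LSK minus GMP -0.11 and Ptprca minus NSG 0.15 log2, and the largest clone between hosts 7.01 points. The inverse Simpson index gave 0.10 log2 for effective clones between hosts. For detected clones, LSK minus GMP, minima of 10 CPM and any value above 0 gave -0.060 and -0.13, Ptprca alone 0.34, NSG alone 0.22 and values relative to the pool 0.12 log2. Effective clones, LSK minus GMP, were -0.13 in NSG alone and -0.057 relative to the pool. The largest clone, LSK minus GMP, was 6.48 points in Ptprca and -3.40 in NSG alone, and between hosts 8.98 in LSK recipients, -0.89 in GMP recipients and 3.85 without the 8 libraries. NSG alone gave 0.50 for the LSK share against the pool. Spearman correlation gave 0.0774 for similarity within mice. The share of mCHERRY_2_Barcode_283858 in GMP recipients was 23.6% in bone marrow and 32.5% in spleen.

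With each mouse left out, the LSK share against the pool ranged from -0.27 to 0.049, that between hosts from -1.27 to -0.81, and the largest clone between hosts from 2.58 to 4.26 points. Clones called in competition ranged from 0 to 3 (LSK, Ptprca; 1 without mouse 2, 2 without mouse 18, 3 without mouse 20), 0 to 7 (GMP, Ptprca), 0 to 2 (LSK, NSG; 2 without mouse 10) and 0 to 2 (GMP, NSG), and GMP clones called between hosts from 30 to 48.

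CPM as deposited, in which the competitor takes part of the total, called 28, 10, 6 and 11 clones in these 4 competition comparisons, all lower. For GMP clones in Ptprca, bone marrow gave 1, and spleen, a pseudocount of 1 CPM, no filter, a mean at or over 1000 CPM, edgeR, edgeR with TMM and the 8 libraries left out gave 0 each. For GMP clones in NSG, spleen, a pseudocount of 100 CPM and no trend gave 1 each, and bone marrow, no filter, edgeR, edgeR with TMM and the 8 libraries left out gave 0 each. Median centring gave 4 and 5, all higher. Between hosts, LSK clones called were 22 in spleen, 17 at a mean of 1000 CPM, 36 with edgeR, 24 with TMM and 19 with centring. GMP clones called were 25 in spleen, 8 at a mean of 1000 CPM and 28 without the 8 libraries.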

Other observations

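The tests of single clones by tissue were planned before their results were seen, and the joint tests of the 12 leading clones were chosen after. In Ptprca mice the tissues held the same leading clones in different proportions. GFP_Barcode_2255 made up 0.706% ± 0.416 of the LSK library in bone marrow and 6.99% ± 1.35 in spleen, and GFP_Barcode_1859 34.4% ± 7.86 and 53.6% ± 6.60, each higher in the spleen of 7 of 7 mice (SD, n = 7). GFP_Barcode_8037 was the reverse, with 4.25% ± 3.42 in bone marrow and 1.21% ± 0.476 in spleen, higher in the marrow of 7 of 7. Among GMP clones, mCHERRY_2_Barcode_4128 held 10.8% ± 2.66 of its library in marrow and 2.49% ± 1.12 in spleen, and mCHERRY_2_Barcode_1204592 12.5% ± 1.69 and 5.85% ± 1.87, each higher in the marrow of 8 of 8 mice, while mCHERRY_2_Barcode_283858 held 20.7% ± 3.52 and 33.5% ± 2.41, higher in the spleen of 8 of 8 (SD, n = 8). Of the 12 leading clones, 6 moved the same way in every Ptprca mouse and 0 of 12 did so in every NSG mouse.

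A hypothesis is that leading clones differ in how they divide between marrow and spleen. Of the 24 clone and host pairs, 0 passed an exact sign-flip test after adjustment, the lowest adjusted p being 0.0625. That count does not decide it, since 7 or 8 mice allow no exact p below 0.0156 or 0.00781, which so few pairs at that limit cannot bring under the threshold after adjustment for 24. Taking the 12 clones jointly and flipping the tissues of whole mice, the mean absolute log2 difference in Ptprca mice was 0.97 against 0.39 over all flips (exact permutation p = 0.000977, the smallest 11 mice allow). In NSG mice it was 0.53 against 0.41 (exact permutation p = 0.134). The Ptprca value is in line with such a division of clones, and the difference between hosts in this joint value was not tested.

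The 10 largest clones of the LSK pool held 18.1% of it and 14% ± 1.40 (SD, n = 3) of the LSK recipients' reads in Ptprca and 20.1% ± 6.62 (SD, n = 4) in NSG mice, and only GFP_Barcode_7785 among the 10 exceeded its pool share in either host. Of the 10, 1 stayed under 100 CPM, by the mean of the tissues, in all Ptprca and 5 in all NSG recipients of LSK cells. The largest, GFP_Barcode_13743, went from 2.55% of the pool to 0.0316% ± 0.0223 in Ptprca mice (SD, n = 3). The 10 largest GMP pool clones went from 20.4% to 44% ± 3.17 in Ptprca and 45.7% ± 2.24 in NSG mice (SD, n = 4), through mCHERRY_2_Barcode_626161, mCHERRY_2_Barcode_1204592 and mCHERRY_2_Barcode_4128. Of 679 LSK pool clones at or over 100 CPM, 162 reached that level in a Ptprca and 65 in an NSG recipient, as did 139 and 52 of 607 GMP pool clones.

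The clone GFP_Barcode_148344 was large in 1 mouse only. It made up 1.05% of the LSK pool and held 28.9% of the bone marrow and 3.89% of the spleen of NSG mouse 9 and at most 0.0227% in any other library of a mouse given LSK cells. This clone was chosen after its values were seen.

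Calls of single clones were compared with those of other splits of the same mice. The 55 LSK clones called between hosts were reached by 1 of 35 splits, the real one (highest other 10), and the 49 GMP clones also by 1 of 35 (highest other 6). That share is under 0.05, but it is the smallest these splits allow and was not adjusted for the 6 comparisons. For the 2 GMP clones called in competition in Ptprca mice, 2 of 35 splits gave as many (highest other 2), and the same held in NSG mice (2 of 35, highest other 2), so chance is not excluded there. For LSK clones in competition the real count was 0 in both hosts, which all 35 of 35 splits reach (highest other 1 in each).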
